A study of Mus musculus with 12 samples.

How the data were processed

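MYC and MAX ChIP-seq peak lists of RAW264.7 cells were analysed. Per the labels' protocols, cells were crosslinked with 1% formaldehyde for 15 min and libraries were sequenced as single-end reads of 50 bp. The 12 libraries fall into 3 kinds (MYC, MAX and input) at 4 treatments with 1 library each, and group membership was taken from the sample titles. FastQC, Bowtie2 2.3.4.1 and MACS2 2.1.1.20160309 are named in the submitters' processing notes, as are the genome builds mm10 and GRCm38, which are the same assembly. How input was used in calling, the calling thresholds and the treatment of duplicate reads are not given in the sources used here.

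The 8 deposited peak lists hold, per row, a position, the names of joined peaks and a score, which is the authors' own value for the peak. In every row peaks from 3 call sets, numbered 3, 5 and 7 in the names, are joined, and the deposited score times the number of joined peaks differs from a whole number by at most 1.09e-11 in any row, as for a mean of member scores. Whether the call sets are separate cultures or separate settings is not stated. The treatment protocol mentions replicates, while the labels list 1 library per antibody and treatment. The lists of MYC and MAX carry different tags, so numbers were compared between treatments within an antibody only. Overlaps between MYC and MAX lists depend on how both were called. The score served to rank and filter peaks within a list, and ranks break ties by chromosome and start. Starts were raised by 1 to give positions counted from 1, on the assumption that the lists follow the BED convention.

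The gene table used here (GRCm38.p6) gives the extent of 21887 protein-coding genes on chromosomes 1 to 19, X and Y, without strand. The planned promoter window of 1 kb around the transcription start was therefore replaced by 1 kb on either side of both annotated ends of a gene. A peak at a gene end can be a promoter or a 3' end. A promoter inside the outermost extent of a gene is missed, and a peak between neighbouring genes counts for both. No genome sequence was used, so E-box content was not analysed here.

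Overlap means at least 1 bp shared. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. The random level is the mean over placements of the peaks at uniform positions on their own chromosome, 100 placements for MYC lists and 10 for MAX lists. Gene lists were tested within each library with two-sided Fisher's exact tests, list genes against all other protein-coding genes, with Benjamini-Hochberg adjustment over 176 tests (22 lists in 8 libraries). Among genes with a MAX peak, lists were tested for MYC peaks in the same way over 88 tests. A list passed at an adjusted p below 0.05. Treatment changes of a list in MAX were set beside 10000 random lists drawn from genes with a MAX peak in any treatment. Each random list held as many genes as the list has members with such a peak. Random lists were not matched for peaks in the reference treatment, so a percentile also reflects how many members had a peak there. The comparison with random lists was added after the data were seen, and it describes single libraries and is not a test between treatments. Of 764 list entries 760 matched the gene table (Mx1, Mx2, Trac and Tf did not).

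Gene lists, the Fisher's exact tests on them and the rule for named genes were fixed before the data were examined. The rule takes genes at the 10 highest-ranked peaks of each list with a gene end, at up to 10 gained and 10 lost peaks per comparison, up to 4 bound and 4 unbound members of each gene list, 11 regulators named in advance, and every gene of a list of 30 or fewer peaks. Other members of gene lists, non-coding genes and peaks inside genes were named after their values were seen. Alternatives covered windows of 0.5 and 2.5 kb, stricter scores, equal numbers of top peaks, stricter overlap and a background of MAX-bound genes. Added after the data were seen were leaving out peaks under 100 bp, whole gene bodies with 1 kb around them, ends of genes of any biotype and equal numbers of widest peaks.

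Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The code was tested on simulated data. With 60.0% of 8839 placed peaks set onto a randomly placed copy of the RANKL MAX list, 60.1% were recovered, with 0 differences from bedtools 2.31.1. With 3 lists given an extra 20% of bound genes in each of 50 simulations over 21887 genes, 90% of them were called at the MYC untreated background and 21.3% at the higher MAX untreated background. Lists without added genes were called in 0.445% and 0.111% of cases.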

Results

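Binding of the transcription factor MYC and of its partner MAX was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in RAW264.7 cells, a mouse monocyte and macrophage line. MAX pairs with MYC, with the MXD, MNT and MGA proteins and with itself, and the pairs bind E-box DNA. The line turns into osteoclasts, the cells that resorb bone, when given RANKL, a cytokine of the TNF family. Cells were left untreated or were kept for 4 h with RANKL at 50 ng/ml, with the I-BET inhibitor at 500 nM, or with both. I-BET compounds occupy the bromodomains of the BET proteins, which otherwise hold on to acetylated histones. Each of the 2 antibodies has 1 peak list for each of the 4 treatments. The 4 input libraries have no peak list of their own and were not used here. With 1 list per antibody and treatment, differences between treatments have no replicate check and carry no p-value.

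The MYC lists held 312 peaks in untreated cells, 299 with RANKL, 136 with I-BET and 11 with RANKL and I-BET. The MAX lists held 8839, 10889, 36785 and 6307 peaks in the same order. Each listed peak joins calls from 3 sets of peaks, whose nature the labels do not state. The highest call number among joined peaks gives a spread between these sets: 512 to 618 for MYC untreated, 554 to 889 with RANKL, 142 to 226 with I-BET and 21 to 23 with both. For MAX it was 10410 to 12541, 13682 to 16034, 38167 to 43064 and 7892 to 9483. Read depth is unknown from these files.

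**Figure D1:**
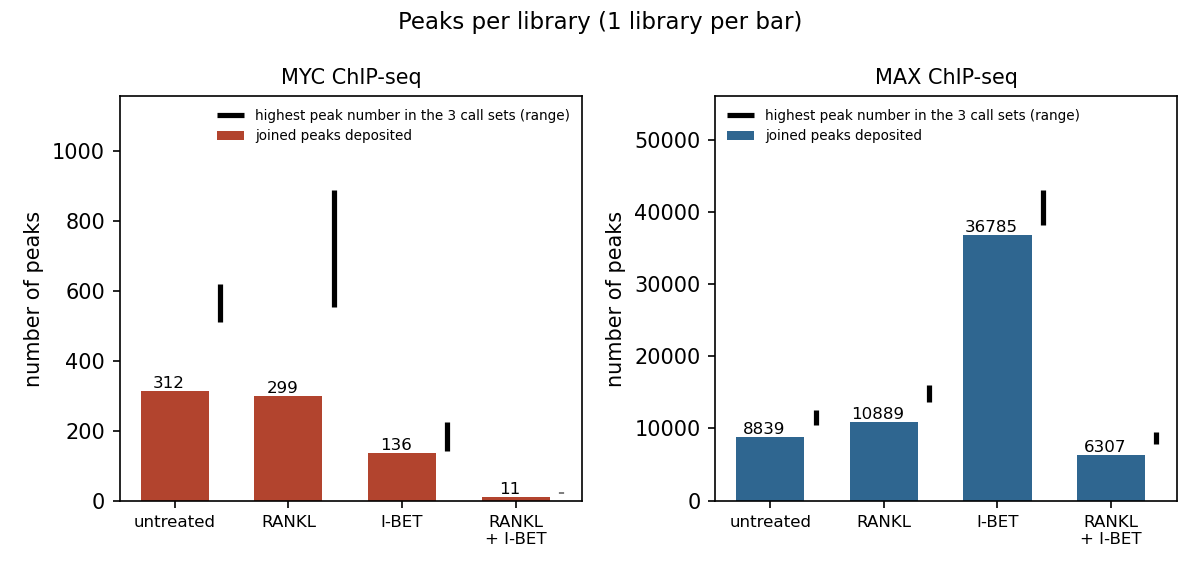
Number of listed peaks (bars, vertical axes from 0) for each treatment, MYC on the left and MAX on the right, each bar being 1 list. Black lines span the highest call numbers of the 3 joined sets. MYC has 312 listed peaks in untreated cells and 11 with RANKL and I-BET, and MAX is highest, at 36785, with I-BET alone.

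In untreated cells MYC lay mostly at gene ends, and genes for ribosome building and protein synthesis had a MYC peak more often than other genes. Of the 312 peaks, 191 were within 1 kb of an end of a protein-coding gene (61.2%, exact 95% interval 55.6 to 66.7), against 3.86% when the peaks were placed at random, and 229 genes had such a peak. Ribosome biogenesis genes had a MYC peak in 13 of 55 cases (23.6%, adjusted p = 2.22e-13, two-sided Fisher's exact test against all other protein-coding genes), among them Ncl (nucleolin), Nop58 and Nop56 (box C/D snoRNP proteins), Gnl3 and Polr1b (a subunit of RNA polymerase I). Cytosolic ribosomal protein genes followed with 11 of 61 (18.0%, Fisher's exact test, adjusted p = 2.50e-10), including Rpl32, Rpl13a and Rpl5. Nucleotide, one-carbon and polyamine synthesis had 3 of 36 (Atic, Srm and Nme1) and translation factors 3 of 38 (Eif3a, Eif3b and Eif5a), with adjusted p = 0.0157 and 0.0181 in Fisher's exact test. These last calls ended when the background was restricted to genes with a MAX peak (Fisher's exact test, adjusted p = 0.278 and 0.294), and the translation factors had 0 peaks in the higher-scoring part of the list. The tests compare genes within 1 library, and genes are not replicates.

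The highest-ranked untreated MYC peak by the authors' score lay on chromosome 5 (142367479 to 142367951, mm10), at the end of the non-coding gene Gm31068, and peaks overlapped it in all 8 lists. Rank 2, 4381 bp wide, fell on the ribosomal RNA locus Rn18s-rs5 on chromosome 17 (39842984 to 39847364). Input was not used here, so whether reads pile up at this locus without MYC was not checked. Rank 3 lay within Ncl on chromosome 1 (86358529 to 86359056). Further down came Pemt at rank 4 (phosphatidylethanolamine methyltransferase), Nudt13 at 7, the shared peak of Fyco1 and Xcr1 at 9, Rrp1b at 10 and G6pc3 at 12. The peak of Arsg and Slc16a6 held rank 13, that of the chaperonin pair Hspd1 and Hspe1 rank 17, Ccnd1 (cyclin D1) rank 18 and Calm3 rank 19. The Nudt13 peak overlapped no MAX peak in any treatment.

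MAX peaks lay at the ends of genes of several functions. Of the 8839 untreated MAX peaks, 52.1% lay at a gene end (51.1 to 53.1, random placement 3.81%), and 5180 protein-coding genes had such a peak. The share was above that of other genes in 12 of the 22 lists fixed before the data were examined. It reached 50 of 55 for ribosome biogenesis, 53 of 61 for cytosolic ribosomal proteins, 33 of 38 for translation factors, 29 of 36 for nucleotide synthesis and 32 of 43 for mitochondrial biogenesis. Lysosome and autophagy genes had 34 of 56 (Fisher's exact test, adjusted p = 2.18e-08) and circadian clock genes 13 of 19 (adjusted p = 0.000187), with Ciart, Per1, Nr1d2 and Nr1d1 at ranks 136, 258, 466 and 961. Aminoacyl-tRNA synthetases had 13 of 20, glycolysis 14 of 25, and cell cycle and replication 21 of 37. The MYC and MAX network itself had 7 of 13, among them Max, Mnt, Mga and Mlxip, and BET and elongation factors had 15 of 37. The call for the network was lost with a window of 2.5 kb (Fisher's exact test, adjusted p = 0.103). The top-ranked MAX peaks lay at Nup85 (nucleoporin), Slc35b1, Mapkapk5, Suclg1, Upf2, Iscu with Sart3, Rbbp5, Lrr1, Gorab and Nsun2 with Srd5a1. All of these were also in the other 3 MAX lists.

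Lists for other cell types had few MAX peaks. Neuronal genes had 0 of 31 in untreated cells (Fisher's exact test, adjusted p = 0.00144), hepatocyte genes 1 of 31 (adjusted p = 0.0125) and MAX-MGA repressed germ cell genes 2 of 31 (adjusted p = 0.0450), all below the 23.7% of other genes. The germ cell genes with a peak were Tdrkh and Zcwpw1. Fibroblast and osteoblast markers had 1 of 20, lymphocyte markers 2 of 19, and neutrophil and dendritic cell markers 2 of 20, none of which passed the test. No MYC peak was listed at a neuronal, hepatocyte, germ cell, lymphocyte or fibroblast gene in any treatment, and 1 of 20 neutrophil and dendritic genes, Xcr1, had 1 in untreated cells and with RANKL through the peak it shares with Fyco1. The low shares in the untreated MAX list did not pass the test in the higher-scoring part of the list, which holds fewer peaks.

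**Figure D2:**
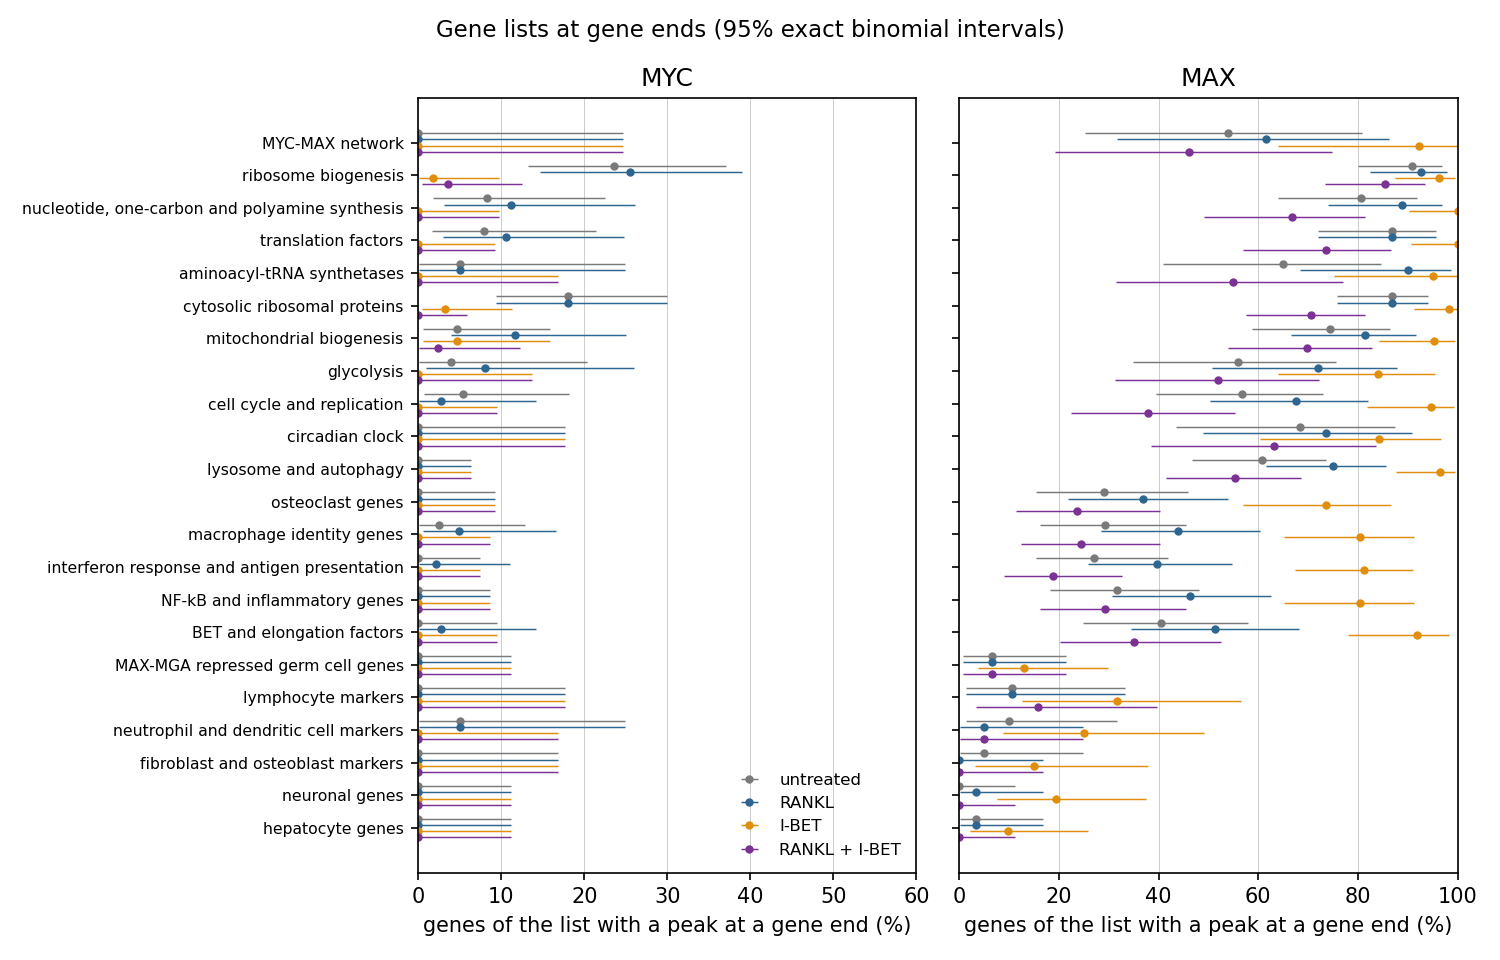
Percentage of the genes of each of the 22 preset lists (vertical axis) with a peak within 1 kb of a gene end (horizontal axis, percent; the MYC panel stops at 60), for MYC on the left and MAX on the right. Points are single libraries coloured by treatment and lines are exact 95% binomial intervals. Ribosome biogenesis stands at 23.6% for MYC and 90.9% for MAX in untreated cells, and neuronal genes at 0 for both.

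MYC is thought to bind DNA together with MAX, and the lists allow the overlap to be counted. In untreated cells 297 of 312 MYC peaks overlapped a MAX peak (95.2%, 92.2 to 97.3), with RANKL 280 of 299 (93.6%, 90.3 to 96.1) and with both compounds 11 of 11 (lower bound 71.5%). With I-BET alone it was 51 of 136 (37.5%, 29.4 to 46.2), and 19.9% against as many top-ranked MAX peaks as the smallest MAX list holds. Random placement gave between 0.0909% and 1.05%. Conversely, 3.29% of the untreated MAX peaks overlapped a MYC peak. This share depends on how both lists were called, and their tags differ. A MAX peak without a listed MYC peak is not shown to lack MYC. The MAX peaks with a MYC peak had a median MAX rank of 413, against 4552.5 for those without a listed MYC peak.

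Among genes with a MAX peak, those of the 2 ribosome lists had a MYC peak more often than others in untreated and RANKL-treated cells. Genes were not matched for MAX rank, and untreated MAX peaks with MYC ranked higher than those without (median 413 against 4552.5). Whether the difference between lists follows from MAX rank was not tested. In untreated cells 26.0% of MAX-bound ribosome biogenesis genes also had a MYC peak, against 4.05% of other MAX-bound genes (13 of 50, adjusted p = 4.20e-06, two-sided Fisher's exact test). For cytosolic ribosomal proteins it was 11 of 53 against 210 of 5127 (Fisher's exact test, adjusted p = 0.000229). With RANKL the shares were 27.5% and 20.8% (Fisher's exact test, adjusted p = 2.25e-07 and 8.52e-05). None of the other 20 lists passed in these treatments. With I-BET, on 2 genes each, mitochondrial biogenesis (Hspd1 and Hspe1, which share 1 peak) and cytosolic ribosomal proteins passed (Fisher's exact test, adjusted p = 0.0202 and 0.0369), and both calls ended with equal numbers of top MAX peaks (adjusted p = 0.0516 and 0.731). With RANKL and I-BET ribosome biogenesis passed, also on 2 genes (Fisher's exact test, adjusted p = 0.0135). Lysosome genes had 0 MYC peaks in every treatment, which allows a share of up to 6.38% of the 56 genes, and 34 carried MAX in untreated cells. The 34 were too few to show a difference from other MAX-bound genes, of which 4.29% had a MYC peak (Fisher's exact test, p = 0.401). Circadian clock and MYC and MAX network genes likewise had 0 MYC peaks in every treatment. In untreated cells 13 and 7 of them carried MAX, too few to show a difference from the 4.28% and 4.27% of other MAX-bound genes.

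RANKL was compared with untreated cells to see what early osteoclast induction does to MYC and MAX binding. The number of MYC peaks was nearly equal (ratio 0.958), but 149 of the 312 untreated peaks were listed again with RANKL (47.8%, 42.1 to 53.5), 163 were not and 152 RANKL peaks had no untreated counterpart. The untreated peaks listed again had a median rank of 108, and those not listed again 200. Of the ribosome biogenesis genes 10 had MYC peaks in both lists, 3 in untreated cells alone (Polr1b, Bop1 and Dkc1, a pseudouridine synthase) and 4 with RANKL alone (Ddx18, Ddx21, Nop14 and Wdr43). Cytosolic ribosomal proteins split into 6, 5 and 5. None of the 7 translation factors was shared, with Eif4a1, Eif4g1, Eef1e1 and Eif1ad listed with RANKL. Mitochondrial biogenesis genes had MYC peaks in 5 of 43 cases with RANKL (Fisher's exact test, adjusted p = 0.000335) and 2 of 43 without. Mrpl23, Timm9 and Twnk (the mitochondrial DNA helicase) were added, and the call ended in the higher-scoring part of the list (Fisher's exact test, adjusted p = 0.367).

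The highest-ranked untreated MYC peaks that had no RANKL counterpart lay at Ccnd1, Fam102b, Zdhhc4, Atf7, Fam3c, Ptma (prothymosin alpha), Specc1, Bcap29 and Lars2. Those listed with RANKL and not without lay at Ctps (CTP synthase, rank 16), Eif1ad with Banf1, Myo19 with Pigw, Tmem185b, Eif4a1, Ptbp1, Nedd8 with Gmpr2, Sec61a1, Adnp and Rps15a. Of the myeloid regulators, Spi1 (PU.1) and Cebpa had a MYC peak with RANKL at ranks 235 and 252, and Klf4 in untreated cells at rank 218. Odc1 (ornithine decarboxylase) and Brd2 had MYC peaks with RANKL at ranks 185 and 170. Prcc, Nop58, Nol8 with Cenpp, Pprc1 (a PGC-1-related coactivator), Mtg1 and Rpl32 were among the top RANKL peaks and were listed in both.

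For MAX, 82.0% of untreated peaks were listed again with RANKL (81.2 to 82.8), 1591 were not, and 3700 RANKL peaks were new to the list. By genes, 4604 had a MAX peak in both, 576 in untreated cells and 1484 with RANKL. Among the preset lists, aminoacyl-tRNA synthetases went from 13 to 18 of 20 by adding Cars, Hars, Kars, Nars and Rars. Lysosome genes went from 34 to 42 of 56 (with Ctsz, Gusb, Neu1, Npc1, Psap, Atp6v1h and Tcirg1 among those added) and macrophage identity genes from 12 to 18 of 41. NF-kB and inflammatory genes went from 13 to 19 of 41, with Nfkb1, Traf2, Birc3, Map3k8, Csf1, Ccl9 and Nfkbie added and Relb no longer listed. The NF-kB list differed from other genes with RANKL (Fisher's exact test, adjusted p = 0.0316), and this call ended in the higher-scoring part of the list (adjusted p = 0.910). The 10000 random lists were drawn from genes with a MAX peak in any treatment, at the number of list members with such a peak. Among them the net gain of the synthetases lay at percentile 95.9 and that of the NF-kB list at 90.7. Cytosolic ribosomal proteins stayed at 53 of 61 (percentile 6.45). Of the 60 with a MAX peak in any treatment 53 already had one in untreated cells, so few could be added and the percentile shows no low gain.

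Osteoclast genes with a MAX peak went from 11 to 14 of the 38 in the list with RANKL and passed the test in neither (Fisher's exact test, adjusted p = 0.707 and 0.365). Traf6 (the adaptor of the RANKL receptor), Oscar, Sh3pxd2b and Tcirg1 were added and Ctsk (cathepsin K) was no longer listed. Among the highest-ranked MAX peaks listed with RANKL and not without were those at Kbtbd6 (rank 1085), Snapin, Adamts6, Mks1, Ccz1, Fam167b, Foxo3, Mtx3 and Fcgr3. Those listed without RANKL and not with it lay at Tmed9 (rank 1408), Tomm7, Abhd17b, Slc39a3, Ypel5, Mindy1, Rnd2, Selenok and Ergic3. At the top of the RANKL list stood Nup85, Iscu with Sart3, Slc35b1, Nsun2 with Srd5a1, Lrr1, Hspa9, Stam2, Ptprs, Hadha with Hadhb, and Eftud2 with Ccdc103.

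**Figure D3:**
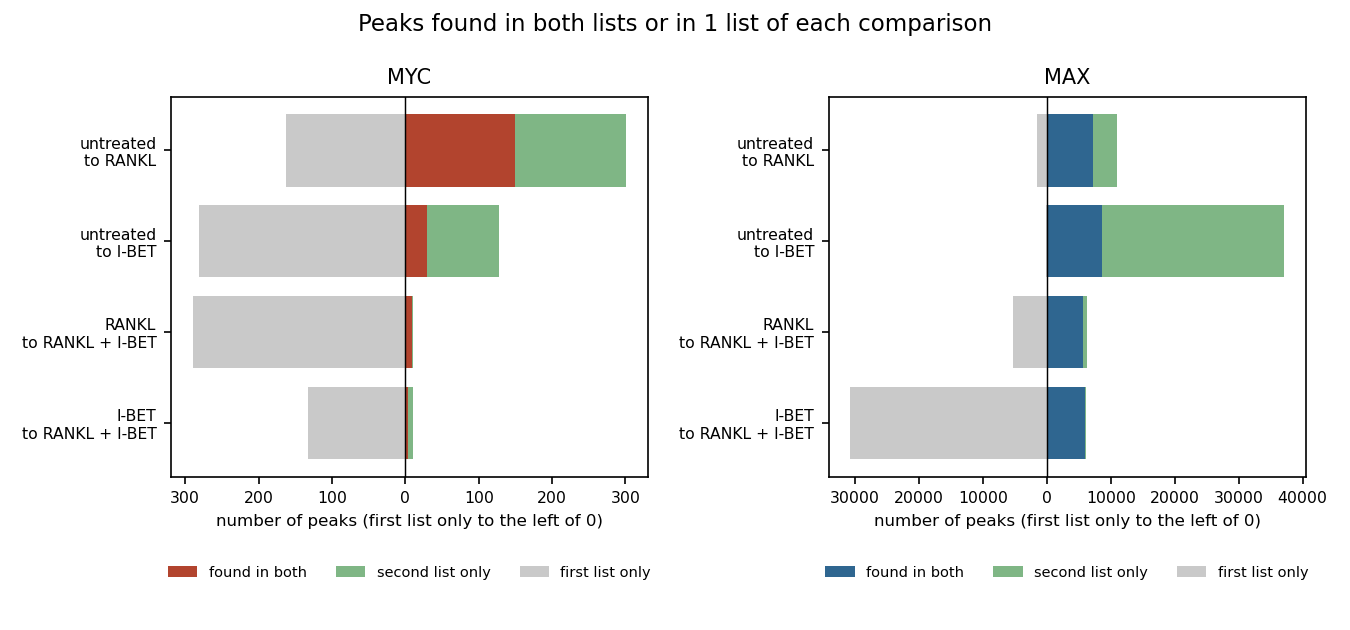
Peaks of each treatment comparison (rows) that overlapped by at least 1 bp, for MYC on the left and MAX on the right. Bars to the right of 0 count first-list peaks found in both lists and peaks of the second list alone, and grey bars to the left count peaks of the first list alone. For MYC 149 untreated peaks were found with RANKL and 163 were not, and for MAX 28448 peaks with I-BET had no untreated counterpart.

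I-BET alone was compared with untreated cells to see how BET proteins bear on MYC and MAX binding. MYC genes almost all left the list: 215 of 229 genes with a MYC peak had none with I-BET, 14 kept one and Rps29 alone was added. The number of MYC peaks was 0.436 times that of untreated cells, and 30 of the 312 untreated peaks were listed again (9.62%, 6.58 to 13.4), with 16.9% shared between equal numbers of top peaks and 2.24% at reciprocal overlap of 50%. The reciprocal value is limited by width, with a median of 72.5 bp with I-BET and 260 bp in untreated cells. Of the 13 ribosome biogenesis genes Ncl stayed, and Nop58, Nop56, Gnl3, Rrp1b, Polr1b, Dkc1 and 6 others did not. Of the 11 ribosomal protein genes Rpl10a stayed. Against all other genes, cytosolic ribosomal proteins (2 of 61 with Rps29) and mitochondrial biogenesis (2 of 43, Hspd1 and Hspe1 with 1 shared peak) were above with I-BET (Fisher's exact test, adjusted p = 0.00251 and 0.00140). Mitochondrial biogenesis had the same 2 genes in untreated cells without passing (Fisher's exact test, adjusted p = 0.147), where 227 other genes had a MYC peak against 13 with I-BET. The share became 0 without peaks under 100 bp for the former and in the higher-scoring part for the latter. Among the other genes that kept a peak were Ppia, G6pc3, Mtg1, Lars2, Ears2 with Ubfd1, Pfn1, Hspd1 with Hspe1, and Hdgf. The highest-ranked losses lay at Pemt, Nudt13, Fyco1 with Xcr1, Rrp1b, Arsg with Slc16a6, Ccnd1, Calm3, Dhrs13, Pcbp1 and Uspl1. The Rps29 peak is 70 bp wide and lies inside the 7SL RNA gene Rn7s1.

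The I-BET list of MYC had another make-up than the others. Its peaks had a median width of 72.5 bp, against 260 bp in untreated cells, and 105 of 136 were under 100 bp (77.2%). At gene ends lay 12 of 136 (8.82%, 4.64 to 14.9). The 85 peaks outside MAX peaks had a median width of 65 bp and a median score of 369, with 0 at gene ends, and the 51 inside had 103 bp, 120 and 12. Without peaks under 100 bp 31 remained, of which 87.1% overlapped MAX and 19.4% lay at gene ends. Of the 10 top-ranked peaks 8 were under 100 bp, such as 96 bp within Dpp9 on chromosome 17 (56199999 to 56200094) and 90 bp within Myo7a, and the peak at rank 10, within Ano2, was 277 bp wide. These 9 were in no other list. The peak at rank 4, on chromosome 17 (4626164 to 4626600), was 437 bp wide and overlapped peaks in the RANKL list of MYC and the I-BET list of MAX.

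**Figure D4:**
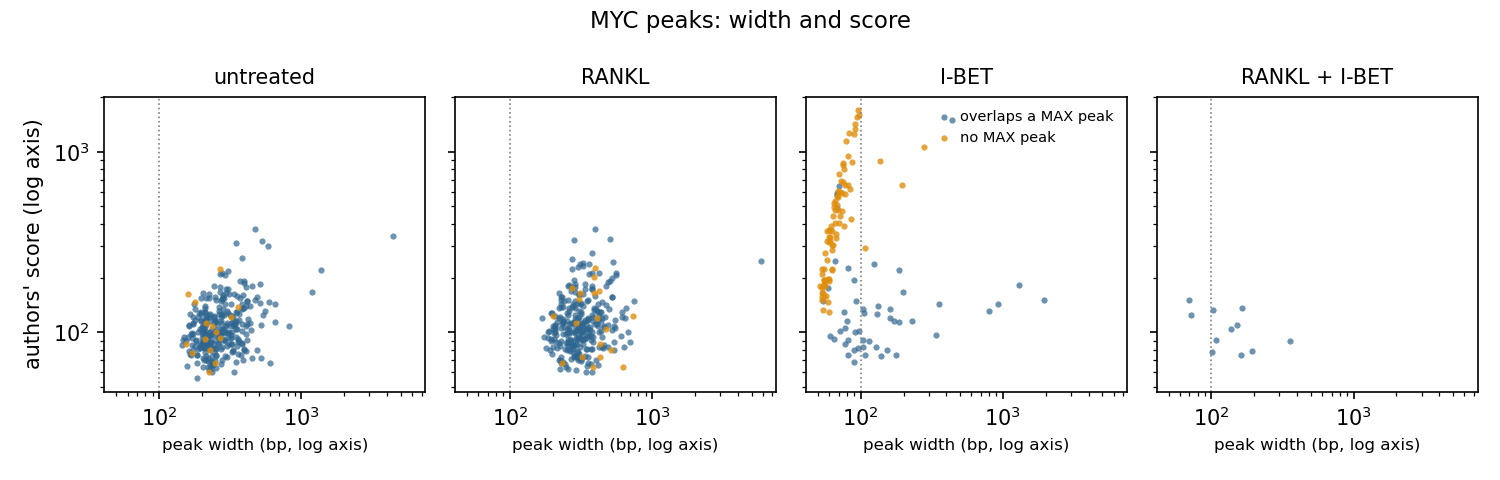
Width of each MYC peak (horizontal log axis, bp) against the authors' score (vertical log axis) in the 4 treatments, with peaks that overlap a MAX peak of the same treatment in blue and the others in orange. The dotted line marks 100 bp. With I-BET 105 of 136 peaks lie left of the line, and in the untreated and RANKL lists 0 do.

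MAX went the other way with I-BET alone. Its list held 4.16 times as many peaks as in untreated cells and overlapped 8615 of the 8839 untreated peaks (exact interval 97.1% to 97.8%). This share was 50.9% with reciprocal overlap of 50% and 59.4% between equal numbers of widest peaks. Matched peaks were wider with I-BET by a median factor of 1.81, which lowers reciprocal overlap. Genes with a MAX peak went from 5180 to 11005, with 5828 added and 3 lost. Lists already near full coverage added few genes (ribosome biogenesis 50 to 53 of 55). Interferon and antigen presentation genes went from 13 to 39 of 48, macrophage identity from 12 to 33 of 41, NF-kB and inflammatory genes from 13 to 33 of 41, osteoclast genes from 11 to 28 of 38 and BET and elongation factors from 15 to 34 of 37. Each of these 5 lists had a higher share than other genes with I-BET, where 50.3% of all protein-coding genes had a MAX peak. Their net gains lay at percentiles 95.6, 84.3, 81.3, 72.9 and 63.6 of random lists drawn from genes with a MAX peak in any treatment, and that of neuronal genes (0 to 6 of 31) at 99.0. Nearly all members with a MAX peak in any treatment had one with I-BET: 39 of 39, 33 of 34, 33 of 33, 28 of 29 and 34 of 34, and 6 of 6 neuronal genes. These percentiles therefore restate how few members had a peak in untreated cells, and do not show where gains with I-BET fell. The top of this list held Ipo13, Gorab, Golga5, Ankle2, Apex1 with Osgep, Rabggtb, Mrps7 with Gga3, Pemt, Ncl and Polr3f with Dzank1. Among the highest-ranked additions were Pofut2, Ddb1 with Tkfc, Zfp593, Adsl, Nceh1, Sec63, Atrn, Mrm3 with Glod4, and Cd3d. Among the 224 untreated peaks not listed again were those near the ends of Msr1, Tmem107, Asxl2, Uck1, Derl1 and Klf6, and all but 3 genes with an untreated MAX peak also had one with I-BET.

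The share of MAX peaks at gene ends was 32.9% with I-BET, and 67.1% among as many top-ranked peaks as the smallest MAX list holds. Ranks in this list have a limit: 17 peaks are listed at a score of 0, and all 17 overlap one of the 500 highest-ranked MAX peaks of each other treatment, at Hspa9, Vars, Lrr1, Slc35b1 and others.

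RANKL with I-BET was compared with RANKL alone to see what BET inhibition does during induction. MYC had 11 peaks against 299, a ratio of 0.0368, and 9 of the 299 RANKL peaks were listed again (3.01%, 1.39 to 5.64). Genes with a MYC peak at an end went from 228 to 4: Pemt (rank 1), Mrpl23, Ncl and Nop58. The others lay at the ends of the non-coding genes Snhg15, Snhg17 (both snoRNA hosts) and Gm31068, and inside Noc2l, Kdm6b, Angptl6 and Gtf2ird2. The Kdm6b peak was in no other MYC list. Ribosome biogenesis (2 of 55) and mitochondrial biogenesis (1 of 43) were above other genes (Fisher's exact test, adjusted p = 0.000167 and 0.0192), and the latter call ended against MAX-bound genes (adjusted p = 0.118). Of the RANKL genes, all 11 ribosomal proteins, 12 of 14 ribosome biogenesis genes, Odc1, Ctps, Eif4a1, Pkm, Hk2, Aurka, Spi1, Cebpa and Brd2 had no MYC peak. Among the highest-ranked losses were also Prcc, Nol8 with Cenpp, Pprc1, Mtg1, Rpl32, Uspl1 and Pcbp1. Between equal numbers of top peaks 36.4% were shared, a count resting on 11 peaks, and reciprocal overlap of 50% gave 0.334%. The reciprocal value is limited by width, with a median of 138 bp with both and 307 bp with RANKL.

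MAX peaks were 0.579 times as many as with RANKL alone. Of the RANKL peaks 51.2% were listed again (50.3 to 52.2), 5310 were not and 662 were added, and 2287 genes left the list while 276 entered it. Cell cycle and replication genes went from 25 to 14 of 37, without Pcna, E2f1, E2f3, Mcm2, Mcm4, Mcm6, Cdc6 and Cdk2 among others (percentile 4.03 of random lists). The random lists were not matched for genes listed with RANKL. Of the 25 genes 11 were lost, against 2287 of 6088 over all protein-coding genes with a MAX peak in RANKL-treated cells. Aminoacyl-tRNA synthetases went from 18 to 11 of 20, and the 5 genes added with RANKL (Cars, Hars, Kars, Nars and Rars) were not listed (percentile 4.34). The loss of 7 of 18 synthetases is likewise to be read beside 2287 of 6088. Their gain with RANKL and this loss rest on the same single RANKL list. Macrophage identity genes went from 18 to 10, interferon genes from 19 to 9 and NF-kB genes from 19 to 12, without Nfkb1, Nfkbia, Traf2 and Csf1, at percentiles 25.1, 15.3 and 33.7 of random lists. Ribosome biogenesis genes held at 47 after 51 (percentile 96.1). The highest-ranked losses lay at Rabl6 with Ccdc183, Mast2, Fkbp2, Lars, Pla2g15, Leng8, Ccdc107, Snapin, Gab2 and Ddx24. The highest-ranked additions were Ank (a pyrophosphate transporter), Rbm38, Got1, Spag9, Dock1, Cd2ap, Ache with Ufsp1, Zdhhc23 with Gramd1c, and Tlk1. Rps12, Hspa9, Blcap, Mapkapk5, Vars and Atp5l were among the top peaks of this list.

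Against I-BET alone, the combination had 0.0809 times the MYC peaks and 0.171 times the MAX peaks. By genes with a MYC peak the ratio was 0.267. Of its MAX peaks 99.0% lay within the I-BET list, and all 4077 genes with a MAX peak also had one with I-BET. For MYC, 3 of the 136 I-BET peaks were listed again (2.21%, and 9.68% without peaks under 100 bp), and Pemt, Mrpl23 and Nop58 had a peak in the combination and not with I-BET. The MAX peaks of the I-BET list with no counterpart were led by Rbm43, Naa35, Wdr74, Cr1l, Yif1b, Kxd1, Slc26a2, Tomm7 and Adsl. The peaks listed in the combination and not with I-BET lay, at gene ends, at Slc18a1, H1f3, Derl1 and Sf3b4.

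The regulators of the osteoclast programme were read in all lists. Myc itself (chromosome 15, 61985341 to 61990361) had no MYC peak in any list and a MAX peak at its end with I-BET alone, at rank 24288 of 36785. The same held for Nfatc1, the master regulator of osteoclast differentiation (rank 11947), Fos (rank 10857) and Prdm1 (rank 11543). Irf8 and Hexim1 had MAX peaks with RANKL (ranks 9500 and 10165) and with I-BET (7120 and 8557), and none in untreated cells or with both. Max, Brd2 and Csf1r (the M-CSF receptor) had a MAX peak in all 4 treatments, as had the AP-1 genes Junb and Fosl2. Acp5 and Mmp9, genes of mature osteoclasts, had none in any list. Ranks come from lists of different lengths and show no change between treatments.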

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

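All tests of explanations in this part were chosen after the results they bear on had been seen. MAX peak numbers went opposite ways with I-BET: 4.16 times as many in cells without RANKL and 0.579 times as many in cells with RANKL. In the same way RANKL went with 1.23 times as many MAX peaks without I-BET and 0.171 times as many with it. Each is the contrast of single libraries, and the difference between the contrasts was not tested.

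The surplus of MAX peaks with I-BET alone was weighed first. A library in which weaker sites were also called remains open: added peaks made up 31.5% of the 9196 highest-ranked peaks of the list and 92.6% of the rest, and peaks matched with untreated ones were wider by a median factor of 1.81, against 1.12 with RANKL and 0.890 with both. The added peaks differed in place from those found again, with 26.7% at gene ends (26.1 to 27.2) against 54.3% (53.2 to 55.3). Higher-scoring MAX peaks lay at gene ends more often than the whole list, in the untreated list as in the I-BET list. A lower share at gene ends was thus also seen among weaker calls. Whether rank alone accounts for the difference was not tested. An inhibitor effect on MAX that holds with and without RANKL also stays open, since the ratio of 0.579 in RANKL-treated cells compares single libraries of unknown depth. An effect of I-BET that depends on RANKL stays open as untested, since treatment and library coincide.

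The loss of MYC peaks with I-BET was weighed next. Loss of these places from every library of the treated cells is argued against, since 90% of the 290 RANKL peaks not listed with RANKL and I-BET overlapped a MAX peak there (86.0 to 93.2), and 99.3% of the 282 untreated peaks not listed with I-BET alone did so in its MAX list. MYC libraries in which only the strongest of the same sites passed remain open: 15.4% of the higher-scoring 156 untreated peaks were listed again with I-BET (10.1 to 22.0), against 3.85% of the other 156 (1.42 to 8.18). Lower MYC occupancy in treated cells would give the same order, and these lists do not separate a weaker library from less bound MYC.

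The MYC peaks outside MAX with I-BET alone were weighed last. Of the 85 peaks 0 overlapped an untreated or RANKL MYC peak (0 to 4.25), or a peak of any other list. Of the 611 peaks of the untreated and RANKL MYC lists 9 lay outside the MAX peaks with I-BET. The 85 were thus not among the listed MYC sites of cells without the inhibitor. Whether MYC bound them there below the calling limit stays open, with 1 library each of unknown depth. Reads piled up at single positions remain a candidate explanation: 95.3% of the 85 were under 100 bp wide (88.4 to 98.7), against 47.1% of the 51 inside MAX (32.9 to 61.5), with reads of 50 bp. Each of these peaks is joined from all 3 call sets, whose nature is not stated. MYC binding without MAX that occurs with I-BET alone stays open as untested, since no reads or motif were examined.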

How the results depend on the processing

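Leaving out peaks under 100 bp, whole genes with 1 kb around them, ends of genes of any biotype and equal numbers of widest peaks were settings chosen after seeing the data, and for the planned stricter score the value of 100 was set then. Of 240 alternative values of main results 154 stayed within their interval or within 1.5 times their count and 86 did not. Of 375 alternative calls of single lists 323 kept direction and side of the threshold, 34 lost the call, 14 gained it and 4 turned. Except where the construction of a setting shows it (narrower windows, fewer peaks or fewer genes tested), the cause was not tested. No paired analysis was possible because each group holds 1 library. Read depth is unknown, so a weaker library and fewer sites look alike in peak numbers. E-box shares and their alternatives (50 bp windows, degenerate motifs, upstream control windows, equal top peaks) were not run.

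A score of at least 100 left 168 MYC untreated, 183 RANKL and 6 RANKL+I-BET peaks. Leaving out peaks under 100 bp left 31 MYC I-BET peaks. MAX numbers stayed within 1.5 times under both settings, and merging on chromosomes 1 to 19, X and Y moved no list beyond that.

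Gene-end shares, in the order untreated, RANKL, I-BET and RANKL+I-BET, became for MAX 47.7%, 46.0%, 28.0% and 52.2% with windows of 0.5 kb, 59.7%, 57.8%, 42.0% and 63.8% with 2.5 kb, 55.5%, 53.9%, 48.1% and 59.96% in the higher-scoring part, 57.9%, 56.7%, 39.8% and 62.6% for genes of any biotype, and 80.4%, 79.7%, 72.4% and 83.1% for whole genes. Equal numbers of top MAX peaks gave 53.8%, 53.2% and 67.1% in the first 3. For MYC, whole genes gave 86.5%, 82.3%, 43.4% and 72.7%, and genes of any biotype 69.6%, 67.9% and 19.1% in the first 3. MYC untreated had 54.8% with 0.5 kb, and untreated and RANKL 69.2% and 68.9% with 2.5 kb. Equal numbers of top MYC peaks gave 45.5%, 54.5% and 0%. MYC I-BET had 1.47% in the higher-scoring part and 19.4% without peaks under 100 bp.

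The MYC share inside MAX peaks with I-BET was 19.9% against equal numbers of top MAX peaks and 87.1% without peaks under 100 bp. With MAX peaks of any treatment it was 99.7% untreated and 97.7% with RANKL.

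The share of reference peaks listed again moved as follows. Reciprocal overlap also falls where peak widths differ between lists, as they do with I-BET. With reciprocal overlap of 50%, MAX had 76.0% for RANKL against untreated, 50.9% for I-BET against untreated, 45.6% for RANKL+I-BET against RANKL and 7.17% against I-BET, and MYC 2.24% for I-BET against untreated and 0.334% for RANKL+I-BET against RANKL. In the higher-scoring part of the reference list, MAX had 94.3%, 98.9%, 75.7% and 31.6% in the same order, and MYC 64.1% for RANKL, 15.4% for I-BET and 0% for RANKL+I-BET against I-BET. With equal numbers of top peaks, MAX had 74.5%, 73.5%, 71.1% and 68.6%, and MYC 16.9% for I-BET against untreated, 36.4% for RANKL+I-BET against RANKL and 0% against I-BET. With equal numbers of widest peaks, MAX had 73.7%, 59.4%, 64.6% and 48.8%, and MYC 15.4%, 0% and 18.2% in these 3 comparisons. Without peaks under 100 bp, MYC had 6.41% for I-BET against untreated and 9.68% for RANKL+I-BET against I-BET.

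The number of lists above other genes fell with a background of MAX-bound genes from 4 to 2 (MYC untreated), from 5 to 3 (RANKL) and from 2 to 1 (RANKL+I-BET). In the higher-scoring part it fell from 2 to 1 for MYC I-BET, and lists below other genes fell to 0 for MAX untreated, 2 for RANKL and 0 for RANKL+I-BET. Among MAX-bound genes, the 2 lists of MYC I-BET became 0 with equal numbers of top MAX peaks and with whole genes, and 1 with 2.5 kb and without peaks under 100 bp. The lists that turned went to 0%: cytosolic ribosomal proteins in MYC I-BET, against all genes and among MAX-bound genes, without peaks under 100 bp, and in the higher-scoring part mitochondrial biogenesis in MYC I-BET and translation factors in MYC untreated.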

Other observations

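The tests on snoRNA genes in untreated cells were set before their results were seen, and those on RANKL-treated cells and on gains with RANKL afterwards. Besides protein-coding genes, MYC peaks lay at hosts of small nucleolar RNAs, which guide the modification of ribosomal RNA. In untreated cells 10 of 291 MAX peaks with a MYC peak lay at the end of a snoRNA gene (3.44%, 1.66 to 6.23), against 44 of 8548 without (0.515%, two-sided Fisher's exact test p = 8.49e-06, adjusted over 8 tests 3.40e-05). With RANKL it was 12 of 280 against 42 of 10609 (4.29% and 0.396%, Fisher's exact test, adjusted p = 6.92e-08). These tests count MAX peaks and were not matched for MAX rank. MAX peaks with MYC ranked higher (median 413 against 4552.5 in untreated cells, 459 against 5580 with RANKL). Whether the excess follows from MAX rank was not tested. Among the untreated MYC peaks at snoRNA genes were those at Snhg15, Rack1, Rpl32 (Snora7a), Rpl13 (Snord68), Snord58b and Nop56 (Snord110). A snoRNA excess may come only from ribosome biogenesis and ribosomal protein genes, many of which carry snoRNAs in their introns. Without MAX peaks at the ends of the listed genes the share with MYC was 1.13% against 0.402% in untreated cells (Fisher's exact test, p = 0.102), which leaves this open there on 3 peaks. With RANKL it was 1.96% against 0.314%, on 5 peaks (Fisher's exact test, adjusted p = 0.00505). The RANKL excess was thus not confined to the ends of listed genes. Peaks inside these genes were not left out, and Rack1, for example, is on neither list, so the explanation stays open with RANKL too.

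Of the 312 untreated MYC peaks, 4 overlapped peaks in all other 7 lists: those at Ncl, Snhg15, Snhg17 and Gm31068. In MAX, 4912 of 8839 untreated peaks were found in all 4 treatments (55.6%), and 59.9% of these lay at gene ends.

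RANKL signals through NF-kB, so gains of MAX peaks with RANKL could be gathered at NF-kB target, macrophage or osteoclast genes. The net gains of these lists (6, 6 and 3 genes) lay at percentiles 90.7, 89.3 and 60.7 of random lists, between the bounds set for and against this explanation, which stays open.

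In the MAX list with I-BET, 17 of 36785 peaks have a score of 0, their median width is 1014 bp, and each of the 17 overlaps one of the 500 highest-ranked MAX peaks of untreated cells. The next lowest score in this list is 19.3 and the highest 3207, and no other MAX list has a score of 0.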
